A study of Rattus norvegicus with 3 samples.

How the data were processed

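RNA was measured in 3 soft tissues from the upper molar region of male Sprague-Dawley rats, 1 array per tissue. Per the labels, the tissues were peri-implant connective tissue (PICT), taken around a titanium alloy implant set into the socket at the time of extraction; periodontal connective tissue (PCT), taken around a natural molar; and oral mucosal connective tissue (OMCT), taken where a molar had been extracted and no implant set. The animals were 9 weeks old at harvest, which for PICT and OMCT was 4 weeks after surgery, per the labels. The sample labels give rat for all tissues, while the series' design text once writes mice for PCT; the samples are treated here as rat. The number of animals behind each array is not given in the sources used here.

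Per the labels' protocols, the connective tissue was collected by laser microdissection, which lifts a chosen area out of a tissue section, and total RNA was purified on RNeasy columns. The same protocols state that RNA was amplified and biotin-labelled with the GeneChip 3'IVT Express kit, which primes from the poly(A) tail so that signal weakens away from the 3' end. The array type, a rat GeneChip, comes from the labels. The deposited values are intensities on a linear scale, 1 per probe set (a group of short probes read together), as their range from 0.0124 to 13104 and skew show. How the authors summarised probes into these intensities, and whether they scaled the arrays to each other, is not given in the sources used here. The trimmed mean intensity (without the lowest and highest 2% of probe sets) was 139.8 in PICT, 91.0 in PCT and 144.6 in OMCT, so the deposited arrays do not share a common mean.

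The table held 31099 probe sets. Gene names came from the platform annotation supplied with the series, dated 2016, in which 20832 probe sets had 1 gene symbol, 436 had several and 9831 had none. Of the 20826 named probe sets that are not controls, 20758 were matched by gene ID to a RefSeq gene table of assembly GRCr8, and 0 symbols had to be updated. Probe sets with several symbols or none were left out of the gene comparisons. Each gene was represented by the probe set with the highest mean log2 value over the 3 arrays, which left 14217 genes, 4525 of them with more than 1 probe set. Genome coordinates were not used, since the build behind the probe annotation is not given in the sources used here.

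Values were taken as log2(intensity + 8.56), where 8.56 is the 20th percentile of all values. A fold on this scale understates the difference of low genes. A gene was counted as higher or lower when its log2 difference was at least 1 (2-fold) and the brighter of the arrays compared lay at or above that array's median probe set. The design set no further scaling between arrays as the main setting. Because the array medians differed by up to 0.62 on the log2 scale, differences are also given relative to the array medians (each array's median log2 value subtracted), and values of single genes and gene lists in the text are these relative log2 differences unless "as deposited" is written. Centring had been set beforehand as a check only; its use for the printed values was chosen after the lower PCT median was seen. Very bright genes, such as Krt5 and Krt14, lie near the top of the intensity range, where differences are compressed.

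With 1 array per tissue there is no spread between replicates, so no test between tissues was run and no p-value or SD between animals exists; the interval and the SDs given later are taken over genes or probe sets; the number of arrays limits the precision. Technical spread was gauged from genes with several probe sets: the SD of the log2 difference between probe sets of 1 gene was 0.44 for PICT against PCT, 0.40 for PICT against OMCT and 0.41 for OMCT against PCT. Among genes past the 2-fold rule with several probe sets, all probe sets had the same direction in 92.0%, 93.6% and 95.7% of genes for these comparisons. The array maker's 9 hybridisation control probe sets differed by a median of 0.16 between PICT and PCT, -0.03 between PICT and OMCT and 0.21 between OMCT and PCT.

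Gene lists for 38 pathways and cell types were described by the median difference of the members whose mean level lay above the median of all genes. The median was placed as a percentile among 10000 random lists of the same size, matched on mean level in 20 bins. A list was said to stand apart below percentile 2.5 or above 97.5; this describes these arrays and is not a test. In 8 lists fewer than 3 members lay above the median level and no percentile was computed. Over the other lists and the 3 comparisons, 58 of 90 medians stood apart, where random lists of unrelated genes would give 4.5. Lists share members and the comparisons share arrays, so the medians are not independent and this excess measures no error rate. The counts of members past the 2-fold rule cover all measured members, dim ones included.

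The genes named in the text follow a rule: Lbp and Sod3; the 10 genes with the largest difference in each direction in each comparison, and in PICT against both other tissues, whose probe sets at or above the median level all pointed the same way, without uncharacterised symbols; up to 4 members per list with the largest difference; and any antioxidant or lipopolysaccharide-list member past 2-fold. Any gene named outside the rule is marked as chosen after its values were seen. The groups, the comparisons, the rules of size, the gene lists, the rule for named genes and the alternative settings were fixed before the data were examined.

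The counting rule and the list percentiles were tested on simulated arrays drawn from the real mean levels. Noise was added so that the difference between the arrays compared had an SD of 0.4. Then 200 genes were altered, all drawn from genes at or above the median level. The shares of altered genes counted therefore do not cover dimmer genes. In the simulation of PICT against PCT, 98% of the genes altered 4-fold and 46% of those altered 2-fold were counted in the right direction, and 0.685% of 14017 unaltered genes were counted. The simulated noise is that between probe sets of 1 gene, without spread between animals or an offset between arrays, so this share is not a rate of false counts for real tissue samples. For PICT against OMCT these shares were 98%, 60% and 0.770%, and for OMCT against PCT 98%, 60% and 0.799%. Of 1000 random lists, 5.7%, 4.8% and 5.3% stood apart in the 3 simulations, and of 20 shifted lists 19, 20 and 19 did.

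Counts of genes were recomputed with arrays centred on their medians, quantile normalization, cyclic loess, no level rule, a level rule at the 75th percentile, a floor at the 20th percentile, the mean of a gene's probe sets, without probe sets whose ID ends in _x_at or _s_at, a pseudocount of 1, a pseudocount at the 50th percentile of all values (48.4), and a z-score rule (over 2 SDs from the 500 genes nearest in level, and at least 1.5-fold). Differences of Lbp, Sod3 and other named genes were recomputed under those settings other than the level rules and the z-score rule, and list percentiles under all but the z-score rule. For the lists, the level rule set which genes were members and which were drawn at random. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used throughout, and R 4.3.3 with limma 3.58.1 for quantile and loess scaling.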

Results

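Gene expression was measured on 1 array per tissue. The tissues were labelled as connective tissue around an implant (PICT), around a natural tooth (PCT) and at a healed extraction site (OMCT). Epithelial keratins were bright on all arrays, so the RNA was not from connective tissue alone. In PICT, PCT and OMCT, Krt5 had an intensity of 7965, 9565 and 8595, and Krt14 of 7492, 8911 and 6894. Both were named here after their values were seen. The median intensity over all probe sets was 56.5 in PICT, 34.3 in PCT and 57.4 in OMCT. On the log2 scale the array medians lay 0.60 higher in PICT than in PCT and 0.62 higher in OMCT than in PCT, and PICT minus OMCT was -0.02. The ratio of 3' to 5' control probe sets, which grows as RNA is shortened, was highest in PCT: 2.80 for Hk1, against 1.58 in PICT and 1.97 in OMCT, and 1.46 for Gapdh, against 1.12 and 1.20. Across probe sets the arrays correlated with Pearson's r of 0.942 (PICT and PCT), 0.934 (PICT and OMCT) and 0.923 (OMCT and PCT); these are correlations across probe sets, which are not independent replicates. No difference below has a replicate check. Among the genes named below, Trem2, Mmp3, Tlr7 and Grem1 in PCT, Padi1, Ly6g6c and Stfa3 in OMCT and Apod in PICT did not exceed the highest negative control of their array (5.71, 3.60 and 8.36), so the sizes of their differences from these arrays are not exact.

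The series title names 2 genes whose expression was to be characterised around implants, and both set PICT apart from the other arrays. Lbp (probe set 1387868_at), which encodes lipopolysaccharide-binding protein, the carrier that hands bacterial lipopolysaccharide to CD14, had an intensity of 419 in PICT, 22.4 in PCT and 59.8 in OMCT. Its relative log2 difference was 3.19 against PCT and 2.67 against OMCT. Sod3 (probe set 1368322_at), which encodes the extracellular superoxide dismutase that binds to matrix and removes superoxide outside cells, had an intensity of 19.4 in PICT, 75.2 in PCT and 169 in OMCT, with differences of -2.19 and -2.65. As deposited, the differences were 3.79 and 2.65 for Lbp and -1.59 and -2.67 for Sod3. Each gene has 1 probe set, so no other probes check the value, and the Sod3 signal in PICT lay at percentile 29.6 of its array. With a pseudocount at the median intensity, the as-deposited Sod3 difference against PCT was -0.87, under 2-fold.

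**Figure D1:**
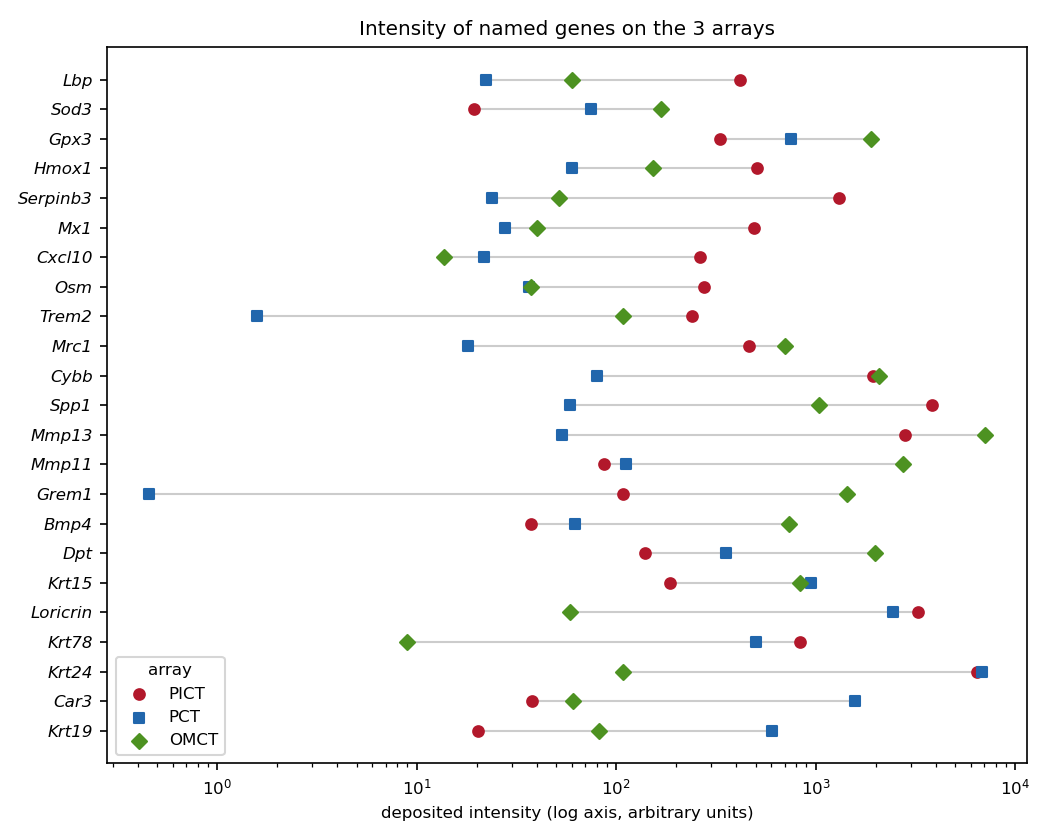
Deposited intensity (log axis, arbitrary units) of 23 named genes, with 1 point per array for PICT, PCT and OMCT and a grey line joining the lowest to the highest. Lbp is brightest in PICT (419) and Sod3 dimmest there (19.4), while Loricrin is dim in OMCT (58.4) and Trem2 in PCT (1.58); the arrays are not scaled to each other and PCT is the dimmer array.

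PICT was compared with PCT to ask how tissue around an implant differs from tissue around a tooth. Genes of macrophages and of matrix breakdown were far higher in PICT. Spp1 (osteopontin, a secreted phosphoprotein of bone and macrophages) had an intensity of 3839.8 in PICT and 58.5 in PCT, a relative log2 difference of 5.24. Mmp13 (collagenase 3) stood at 2793 and 53.9, a difference of 4.89. Trem2 (a lipid-sensing receptor of macrophages and osteoclasts) differed by 4.02, Cybb (the catalytic subunit of the phagocyte NADPH oxidase) by 3.86, Tyrobp (the signalling partner of Trem2) by 3.79, Clec7a (the beta-glucan receptor dectin-1) by 3.69 and Bcl2a1 (a survival factor of leukocytes) by 3.64. Serpinb3, a squamous epithelial protease inhibitor, differed by 4.75.

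Of 26 measured macrophage and monocyte genes, 16 were at least 2-fold higher in PICT than in PCT, 0 were lower and 10 were neither; the list median of 2.32 lay at percentile 100. Besides Trem2 and Tyrobp, Mrc1 (the mannose receptor) differed by 3.54 and Ctss (the lysosomal protease cathepsin S) by 3.22. Among 26 matrix proteases and inhibitors, 14 were higher and 0 lower (median 1.20, percentile 100), with Mmp3 (stromelysin 1) at 3.37 and Mmp9 (gelatinase B) at 2.80. In the osteoclast list 4 of 8 genes were higher and 0 lower (median 1.09, percentile 100), among them Ctsk (cathepsin K) at 1.42, Tnfrsf11a (the receptor RANK) at 1.24 and Itgb3 at 1.09. The osteoclast list also stood apart in OMCT minus PCT (median 1.21, percentile 99.9), with 5 genes higher and 1 lower. In PICT minus OMCT it did not (median -0.45, percentile 3.995), so its rise over PCT was not particular to PICT. Markers of neutrophils were higher for 5 of 14 genes and lower for 0 (median 1.47, percentile 100), led by S100a9, a calcium-binding alarmin, at 3.48. That median rests on 5 members above the median level, and Mmp9, which is also in the protease and osteoclast lists, is 1 of them.

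Inflammatory genes followed the same direction in this comparison. In the interferon list 12 of 22 genes were higher and 1 was lower (median 1.04, percentile 100). Mx1 (an antiviral GTPase) differed by 3.17, Isg15 (a ubiquitin-like modifier) by 2.63, Mx2 by 2.25 and Irf7 (a transcription factor for interferon genes) by 1.94; the lower gene, Bst2, was at -1.09 and was named after its value was seen. Of 38 cytokines and chemokines 11 were higher and 3 lower (median 0.65, percentile 100), with Cxcl10 (a T cell attractant) at 2.57, Ccl2 (a monocyte attractant) at 2.52, Cxcl2 (a neutrophil attractant) at 2.12 and Il1b (interleukin 1 beta) at 2.04. Lipopolysaccharide and Toll-like receptor recognition counted 8 higher and 0 lower genes of 22 (11 and 0 as deposited; median 0.45, percentile 99.8): Lbp, the receptors Tlr7 at 2.24, Tlr1 at 1.80 and Tlr2 at 1.36, the kinase Irak2 at 1.07, and the NF-kB pathway members Tnfaip3 at 1.52, Nfkb2 at 1.15 and Nfkbiz at 1.01. Tlr4, the receptor that lipopolysaccharide signals through, differed by 0.10 and Cd14 by 0.62; both were named after their values were seen.

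The antioxidant list did not stand apart between PICT and PCT (median 0.01, percentile 69.1), with 3 of 29 genes higher, 2 lower and 24 neither; as deposited 7 were higher and 2 lower (median 0.61). Higher were Hmox1 (heme oxygenase 1) at 2.31, Gpx8 (an endoplasmic reticulum peroxidase) at 1.18 and Prdx5 (a peroxiredoxin) at 1.08. Sod3 and Gpx3, which encodes the glutathione peroxidase of plasma and extracellular fluid, were lower, with Gpx3 at -1.77 (intensity 332 in PICT and 755 in PCT). The cellular enzymes Sod1 and Sod2, named after their values were seen, differed by -0.97 and 0.76.

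Genes lower in PICT than in PCT included Car3 (carbonic anhydrase 3) at -5.70, with an intensity of 37.8 against 1575, and Krt19, a keratin of simple and junctional epithelium, at -5.01, with 20.3 against 603. Krt36, a keratin of hair and tongue epithelium, differed by -4.44, Ada (adenosine deaminase) by -3.70, Cdo1 (cysteine dioxygenase) by -3.01 and Fa2h (fatty acid 2-hydroxylase) by -3.18. Endothelial genes were lower for 7 of 21 members and higher for 0 (median -0.76, percentile 0), against 2 lower and 2 higher as deposited (median -0.16), with Plvap (a diaphragm protein of fenestrated capillaries) at -2.26, Cldn5 (an endothelial tight junction claudin) at -1.76, Vwf (von Willebrand factor) at -1.24 and Pecam1 at -1.16. The keratinocyte list had a median of -0.56 (percentile 0) relative to the array medians and 0.04 as deposited, with 3 of 18 genes lower and 0 higher (1 and 1 as deposited); Krt15, a keratin of basal epithelial cells, was lowest at -2.90. Differentiated oral epithelium did not stand apart, at -0.26 relative (percentile 8.29) and 0.34 as deposited, with 0 of 20 genes past 2-fold in either direction (1 higher as deposited).

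Periodontal ligament markers were higher in PICT than in PCT for 3 of 12 genes and lower for 1 (5 and 1 as deposited; median 0.77, percentile 99.9, which rests on leaving out dim members), with Ncam1 (a cell adhesion molecule) at 1.89, Tnn at 1.84 and Postn (periostin) at 1.12 higher and Thbs4 at -2.91 lower. The periodontal ligament list was also higher in OMCT than in PCT (6 higher and 1 lower, median 1.47, percentile 100). Its rise over PCT was thus not particular to PICT. Collagens had a median of 0.29 (percentile 99.6) with 1 of 16 genes higher, Col24a1 at 1.77, and 1 lower, Col14a1 at -1.71. As deposited 4 were higher and 1 lower.

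By the fixed rule of size, 2009 of 14217 genes were higher and 128 lower in PICT than in PCT as deposited, 94.0% of them higher. Relative to the array medians the counts were 566 and 479, 54.2% of them higher, so the split of directions rests on how the arrays are scaled.

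**Figure D2:**
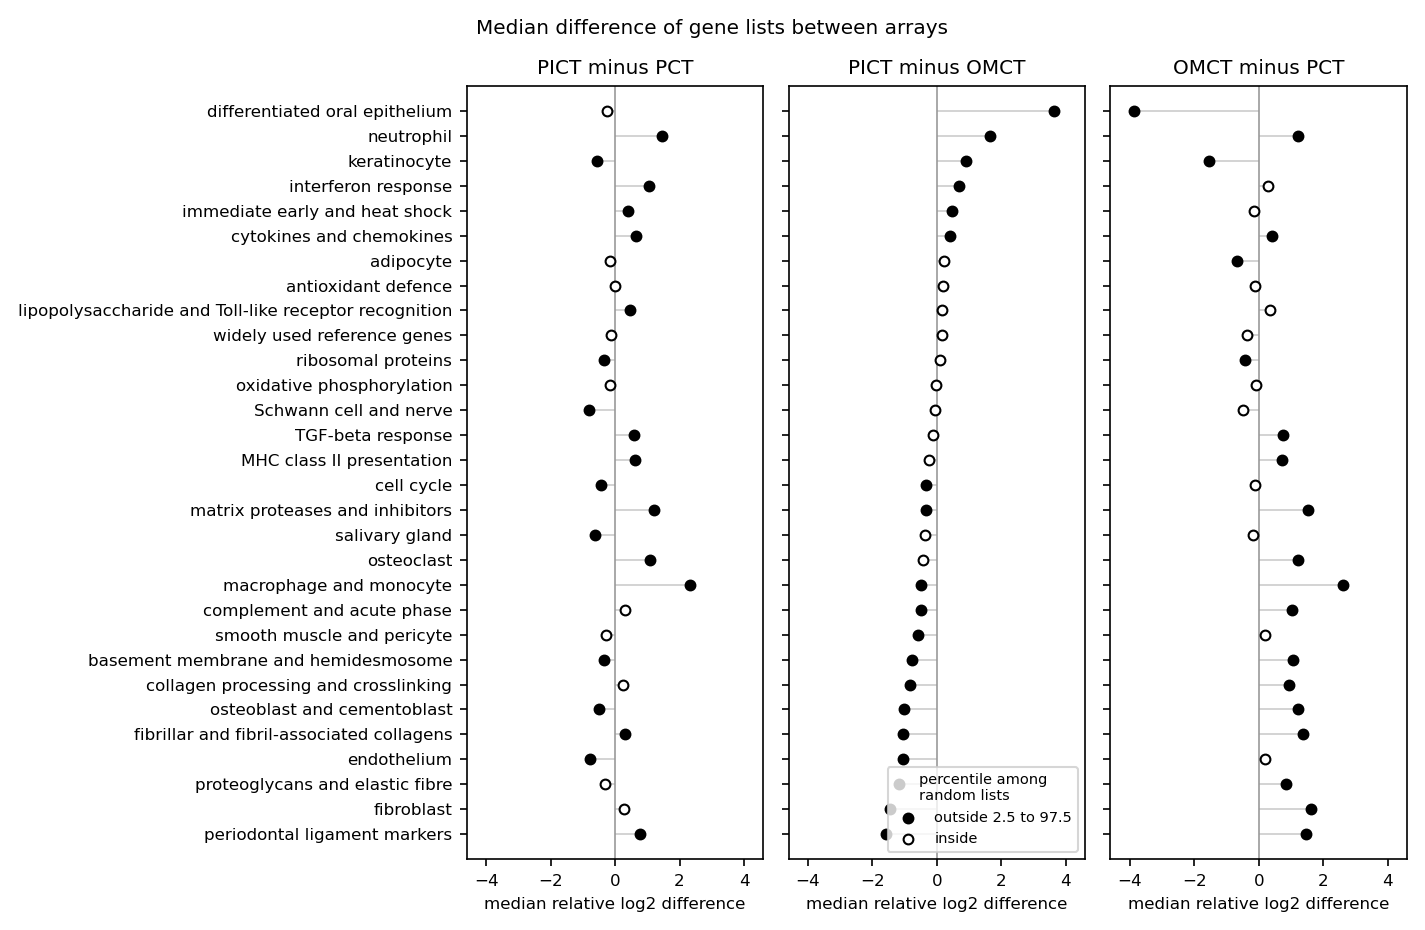
Median relative log2 difference (horizontal axis, log2 units) of the 30 gene lists with at least 3 members above the median level, in 3 panels for PICT minus PCT, PICT minus OMCT and OMCT minus PCT; filled points stand apart from random matched lists and open points do not. Differentiated oral epithelium reaches 3.63 in PICT minus OMCT and -3.88 in OMCT minus PCT, and macrophage genes 2.32 in PICT minus PCT; the as-deposited medians of some lists near 0 in the panels against PCT have the opposite sign, among them keratinocyte (-0.56 relative, 0.04 as deposited) in PICT minus PCT.

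PICT was compared with OMCT to set a socket that received an implant against one that healed without it. Genes of the upper, keratinising layers of epithelium were higher in PICT by the widest margins. Defb4, an epithelial beta-defensin, had an intensity of 1318 in PICT and 4.32 in OMCT, a relative log2 difference of 6.71. Serpina12 (vaspin) differed by 6.69, Padi1, which citrullinates keratins and filaggrin, by 6.14, Krt24 by 5.81, Loricrin, the main protein of the cornified envelope, by 5.64 and Krt78 by 5.62. In the list of differentiated oral epithelium 19 of 20 genes were higher and 0 lower (median 3.63, percentile 100), with Cnfn (cornifelin) at 5.40 and Krt1 at 5.33. Keratinocyte genes were higher for 9 of 18 and lower for 1 (median 0.91, percentile 100), led by Cldn4 (a claudin) at 2.93, while the lower gene was Krt15 at -2.10.

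Matrix and stromal genes were lower in PICT than in OMCT. Mmp11 (stromelysin 3, made by fibroblasts) had an intensity of 87.1 in PICT and 2740.2 in OMCT, a difference of -4.83. Bmp4 (a bone morphogenetic protein) differed by -4.00, Stc1 (stanniocalcin 1) by -3.98, Dio2 (the deiodinase that activates thyroid hormone) by -3.89, Dpt (dermatopontin, a dermal matrix protein) by -3.74 and Grem1 (a secreted BMP antagonist) by -3.61. Collagens were lower for 9 of 16 genes (median -1.05, percentile 0), with Col6a2 at -1.91, and 0 were higher. Proteoglycans and elastic fibre genes were lower for 12 of 24 (median -1.17, percentile 0), with Bgn (biglycan) at -2.48, and 0 were higher. Basement membrane genes were lower for 10 of 20 (median -0.76, percentile 0), with Col7a1 (the anchoring fibril collagen) at -2.31 and Lama2 (a laminin chain) at -2.28, and 0 were higher. Collagen processing genes were lower for 6 of 19 (median -0.84, percentile 0), with Pcolce (an enhancer of procollagen cleavage) at -2.48 and Loxl2 (a crosslinking enzyme) at -2.15. Matrix proteases and inhibitors were lower for 4 of 26 and higher for 2 (median -0.34, percentile 0.92).

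Cell type lists of connective tissue and vessels lay lower in PICT as well. The fibroblast list counted 5 lower and 0 higher genes of 15 (median -1.45, percentile 0), among them Thy1 at -2.12. Periodontal ligament markers counted 7 lower and 0 higher of 12 (median -1.59, percentile 0), with Tnn (tenascin W) at -2.13 and Aspn (asporin) at -1.61. Endothelium counted 11 lower and 0 higher of 21 (median -1.05, percentile 0), with Lyve1, a hyaluronan receptor of lymphatic endothelium and of some macrophages, at -2.96 and Flt4, the lymphatic growth factor receptor, at -2.25. Smooth muscle and pericyte genes counted 5 lower and 0 higher of 17 (median -0.60, percentile 0.21, which rests on leaving out dim members). Macrophage genes were lower for 7 of 26 and higher for 2 (median -0.50, percentile 0.10): the complement subunits C1qb at -2.54 and C1qa at -1.96 were lower, whereas Trem2 was higher at 1.12.

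Several inflammatory lists were higher in PICT than in OMCT. Interferon genes were higher for 8 of 22 and lower for 0 (median 0.69, percentile 100), with Mx1 at 3.38, Isg15 at 3.06, Rsad2 (viperin) at 2.25 and Ifit3 at 2.03. Cytokines and chemokines were higher for 10 of 38 and lower for 3 (median 0.42, percentile 99.7), with Cxcl10 at 3.63 and Ccl6 at 2.82. The neutrophil list was higher for 6 of 14 and lower for 0 (median 1.63, percentile 100); its largest difference was that of Ly6g6c (a Ly6 family surface protein) at 3.74, which was low in OMCT alone (119 in PICT, 152 in PCT and 1.15 in OMCT) like the epithelial genes, and S100a8 at 3.28 is also made by stressed keratinocytes. Lipopolysaccharide recognition did not stand apart (median 0.16, percentile 90.6), although Lbp, Tnfaip3 at 1.18, Irak2 at 1.15 and Tlr1 at 1.07 were higher among 22 genes and 0 were lower. Of 29 antioxidant genes, 1 was higher, Hmox1 at 1.70, and 5 were lower: Gpx7 at -2.88, Sod3, Gpx3 at -2.47, Mt3 at -1.02 and Gpx8 at -1.01. The antioxidant median was 0.18 (percentile 96.6), not apart from random lists.

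As deposited, 566 genes were higher and 660 lower in PICT than in OMCT, and relative to the array medians 590 and 634. What the difference in upper-layer epithelial genes between these sections does to other lists was not tested.

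OMCT was compared with PCT to set a healed extraction site against tissue around a tooth. Grem1 had an intensity of 1435 in OMCT and 0.456 in PCT, where it did not exceed the highest negative control (5.71), so the relative log2 difference of 6.70 is not exact. Mmp13 reached 7086 in OMCT, a difference of 6.21 from PCT. Gsta3l1 (a glutathione transferase) differed by 5.46, Dio2 by 4.91, Adamts12 (a matrix metalloprotease) by 4.40, and the wound and development matrix proteins Tnc (tenascin C) and Tnn by 4.22 and 3.97. Macrophage genes were higher in OMCT for 22 of 26 and lower for 0 (median 2.60, percentile 100), with Mrc1 at 4.11, Tyrobp at 3.62, Ctss at 3.51 and Folr2 (a folate receptor of resident macrophages) at 3.42. Matrix proteases and inhibitors were higher for 19 of 26 and lower for 0 (median 1.52, percentile 100), with Mmp3 and Mmp11 both at 3.89.

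Matrix lists were also higher in OMCT than in PCT. Collagens counted 10 higher and 1 lower of 16 (median 1.38, percentile 100), with Col24a1 at 3.55. Fibroblast genes counted 7 higher and 1 lower of 15 (8 and 0 as deposited; median 1.64, percentile 100), with Thy1 at 2.60 and Pdgfra (a growth factor receptor of fibroblasts) at 2.24. Basement membrane genes counted 10 higher and 1 lower of 20 (median 1.07, percentile 100), and collagen processing genes 8 higher and 0 lower of 19 (median 0.93, percentile 100; as deposited 14 higher and 0 lower, median 1.56). Epithelial genes ran the other way. Differentiated oral epithelium was lower in OMCT for 19 of 20 genes and higher for 0 (median -3.88, percentile 0), and keratinocyte genes were lower for 14 of 18 and higher for 0 (median -1.53, percentile 0; 8 lower as deposited, median -0.91). Defb4 differed by -6.58, Krt24 by -6.50, Serpina12 by -6.08, Krt7 by -5.86, Loricrin by -5.82 and Sprr1a, a cornified envelope precursor, by -5.67.

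Neither the interferon list (median 0.30, percentile 95.4; 1 higher and 1 lower of 22) nor the lipopolysaccharide list (median 0.34, percentile 96.9; 4 higher and 0 lower of 22) stood apart between OMCT and PCT. As deposited, 9 interferon genes were higher and 0 lower (median 0.92), and 8 lipopolysaccharide genes were higher and 0 lower (median 0.96). In the lipopolysaccharide list Tlr7 at 2.65, Tlr2 at 1.57, Cd14 at 1.56 and Ly96 (MD-2, the partner of Tlr4) at 1.39 were higher in OMCT. The antioxidant median was -0.12 relative to the array medians and 0.50 as deposited (percentile 21.5), with Gpx8 at 2.19, Gpx7 at 2.09 and Mt3 (a metallothionein) at 1.07 higher and Txnrd2 (mitochondrial thioredoxin reductase) at -1.14 lower; as deposited 8 of 29 were higher and 0 lower. As deposited, 2501 genes were higher and 298 lower in OMCT, 89.4% of them higher; relative to the array medians the counts were 805 and 684, 54.1% of them higher.

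PICT was also set against both other tissues together. Genes higher in PICT than in either included Serpinb3, with an intensity of 1315 in PICT, 23.9 in PCT and 51.7 in OMCT, and the interferon targets Mx1 (489, 27.8 and 40.0), Isg15 (763, 73.2 and 85.5) and Cxcl10 (264, 21.7 and 13.7). Osm (oncostatin M, an IL-6 family cytokine of leukocytes) differed by 2.05 from PCT and 2.65 from OMCT, G0s2 (an inhibitor of fat breakdown) by 2.33 and 3.12, and Sprr2d (a cornified envelope precursor) by 2.22 and 2.70. Lbp ranked among the 10 largest of this kind. Stfa3, of the stefin A family of near-identical genes, also did, but its value is uncertain: without probe sets that can match several transcripts its as-deposited difference from OMCT was -0.063.

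Genes lower in PICT than in either included Shc4 (a signalling adaptor) at -2.78 from PCT and -3.64 from OMCT, Krt15 at -2.90 and -2.10, Inhbb (the activin beta B subunit) at -2.53 and -2.15, Apod (apolipoprotein D) at -2.42 and -3.67, Acan (aggrecan, a large proteoglycan) at -2.37 and -1.67, and Thbs4 (thrombospondin 4, a matrix protein of tendon and ligament) at -2.91 and -1.66. Sod3 and Gpx3 were in this group too. As deposited, 256 genes were higher and 60 lower in PICT than in both; relative to the array medians 136 were higher and 167 lower. The differences share the PICT array, so a deviation of that array alone would appear in both.

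**Figure D3:**
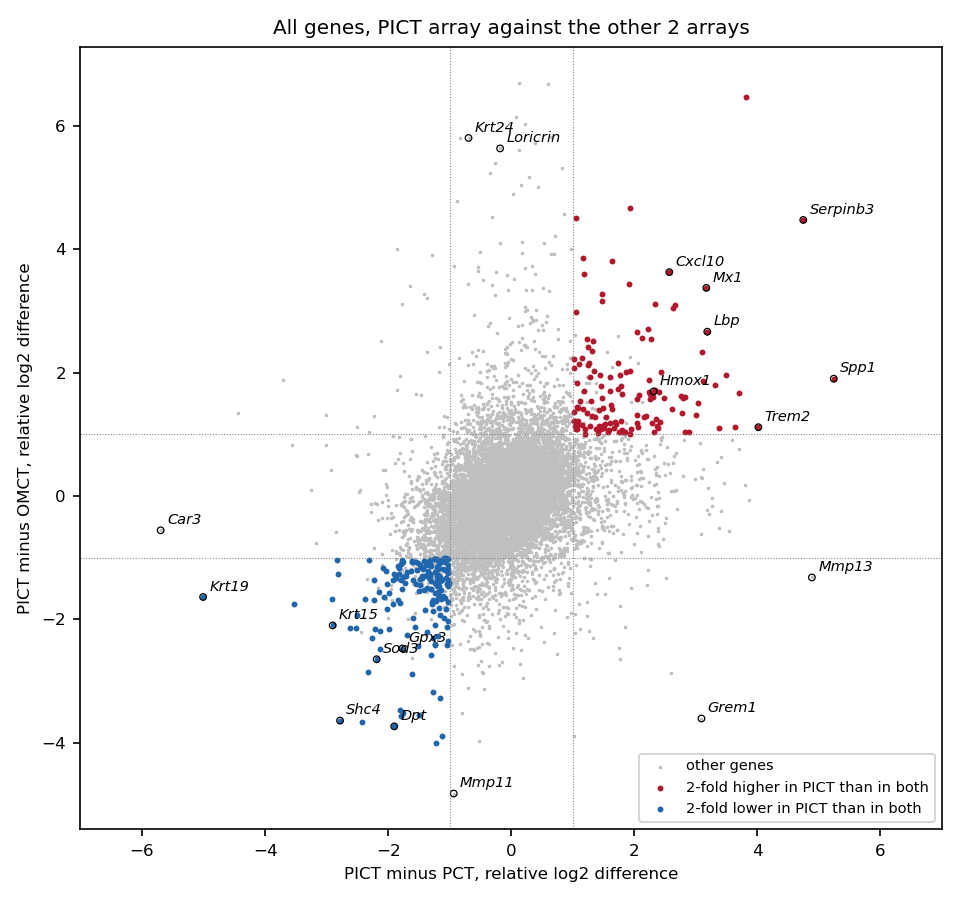
Relative log2 difference of 14217 genes in PICT minus PCT (horizontal axis) and PICT minus OMCT (vertical axis), 1 point per gene, with dotted lines at a difference of 1 in either direction. The 136 genes higher in PICT than in both (red) include Lbp at 3.19 and 2.67, the 167 lower (blue) include Sod3 at -2.19 and -2.65, and Krt24 and Loricrin lie high on the vertical axis alone.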

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

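All tests in this part were chosen after the results were seen. Probe sets without a gene symbol were left out of the comparisons, and some carried a signal that set PICT apart: of 9780 such probe sets, 96 were at least 2-fold higher in PICT than in both other tissues and 52 were lower, relative to the array medians. Probe set 1398576_at had an intensity of 136 in PICT, 11.0 in PCT and 18.9 in OMCT, and 1375509_at had 56.8, 0.364 and 5.26. Probe set 1380384_at had 42.3, 132 and 954, and 1386472_at had 7.82, 58.2 and 67.5. The highest of the array's negative control probe sets was 8.36.

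Genes of the upper epithelial layers were lower in OMCT than in PICT, which bears on how the section was taken. Array brightness is argued against, since the array medians of PICT and OMCT differed by -0.0201 and the list median was 3.61 as deposited. A smaller amount of the whole epithelium in OMCT would lower basal-layer genes alike, yet the median of 10 basal genes was 0.00 against 3.64 for 18 suprabasal genes, a gap of 3.63 (95% bootstrap interval over genes 2.65 to 4.84; genes under an intensity of 5000 only). Of the 12 basal genes listed for this test, 9 are in other lists, and Krt5 (7965 in PICT, 8595 in OMCT) and Krt14 (7492 and 6894) were too bright for it. A candidate explanation that stays open is a thinner or less keratinised epithelium over the healed site, or a section border through its lower layers; with 1 array per tissue these were not told apart.

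Macrophage genes were lower in PCT than in PICT. A dimmer PCT array argues poorly for it, since the lowest list median over 3 scalings was 2.32. Dilution of connective tissue by epithelium in PCT would lower endothelial genes there too, but their median in PICT minus PCT was -0.76 (SD over 18 genes 0.76) and -0.16 as deposited. Smooth muscle and pericyte genes were at -0.29 (0.31 as deposited). Fibroblast genes at 0.26, collagens at 0.29 and keratinocyte genes at -0.56 (0.04 as deposited) had the direction that dilution would give. Their sizes were below the macrophage median of 2.32, so a small dilution is not excluded. More blood in PICT is argued against by Hbb, the beta-globin gene, at -1.47 (intensity 415 in PICT and 765 in PCT) and -0.87 as deposited, where more blood would make it higher. The macrophage list was also higher in OMCT than in PCT for 22 of 26 genes (median 2.60), and PICT minus OMCT had a median of -0.50. The rise over PCT was thus not particular to PICT. More macrophages in PICT than in PCT is a hypothesis that stays open, as does the higher 3' to 5' ratio of the PCT array. Of the 26 macrophage genes, 6 also stand in other lists.

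For Sod3 and Lbp, a different mix of cells in the sections may account for part of the difference. In PICT minus PCT, where Sod3 was at -2.19, a smaller share of fibroblasts is argued against by the median of 7 fibroblast genes at 0.26 (0.86 as deposited, SD over genes 0.90). Dpt, 1 of the 7, lay near Sod3 at -1.90, and of all 15 fibroblast genes measured 1 was higher and 2 were lower. A smaller share of vessel cells and a lower Sod3 per cell cannot be told apart: 28 endothelial and smooth muscle genes had a median of -0.67 (SD 0.80), all 35 genes together -0.42 (SD 0.84), and Sod3 lay under 2 SDs below either when the probe set spread was added. In PICT minus OMCT the 35 genes had a median of -1.08 (SD 0.93) and 2 of them lay as low as Sod3 at -2.65, so a smaller share of these cells cannot be told apart from a lower Sod3 per cell there. As a cause of higher Lbp in PICT than in PCT, more epithelium is argued against, since the median of 37 epithelial genes was -0.40 (SD 0.61) relative to the array medians and 0.20 as deposited, and Lbp lay 3.58 above it on either scale. Against OMCT, where Lbp was at 2.67, more epithelium in PICT and a higher Lbp per cell cannot be told apart: in OMCT minus PCT the epithelial median was -2.21 (SD 1.55) and Lbp lay the other way at 0.52, but under 2 SDs from that median.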

How the results depend on the processing

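Lbp was higher and Sod3 lower in PICT than in both other tissues under the 8 alternatives that apply to single values. Each gene has 1 probe set, so the choices among probe sets could not alter it. With arrays centred on their medians, under quantile normalization and under cyclic loess, PICT minus PCT was 3.19, 3.21 and 3.21 for Lbp and -2.19, -2.15 and -2.17 for Sod3. With a pseudocount at the median, Lbp was at 2.72 against PCT and 2.11 against OMCT, and Sod3 at -0.87 and -1.68, so Sod3 against PCT was no longer past 2-fold; the larger pseudocount shrinks every difference of dim genes. Spread was taken from probe sets of 1 gene, as no replicates exist.

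Counts of genes depended on the scaling of the arrays, which removes the offset of the PCT array, and on the level rule, the pseudocount and the rule of size. Higher and lower in PICT than in PCT were 566 and 479 with centring, 582 and 475 with quantile normalization and 597 and 441 with loess. In OMCT against PCT they were 805 and 684, 799 and 693, and 809 and 675. In PICT against both they were 136 and 167, 141 and 156, and 148 and 152. The level rule at the 75th percentile admits fewer genes: 1239 and 63 for PICT against PCT, 356 and 427 for PICT against OMCT, 1539 and 190 for OMCT against PCT, and 158 and 35 for PICT against both. The pseudocount at the median gave 1060 and 43, 338 and 391, 1419 and 168, and 109 and 19, in the same order. The z-score rule gave the lowest counts of higher genes: PICT had 345 higher genes against PCT, 268 higher and 228 lower against OMCT, and 52 higher and 37 lower against both, and OMCT had 314 higher against PCT. Without a level rule, 198 genes were lower in PICT than in PCT. The remaining 47 recomputed counts stayed within 1.5 times.

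Among recomputed differences of named genes, 433 stayed within the probe set SD, 302 moved further and 1 changed sign: Stfa3 in PICT minus OMCT was -0.063 without _x_at and _s_at probe sets; the cause was not tested, though stefin A copies share sequence. Of the recomputed list percentiles, 849 stayed on their side of the limits, 38 moved inside and 13 moved outside. The 849 include 90 with arrays centred on their medians, which could not move. Centring shifts a list and its random lists alike. Without a level rule, which admits dim members, 11 list medians no longer stood apart: cell cycle, ribosomal, periodontal ligament and salivary genes in PICT minus PCT; osteoblast, complement and smooth muscle genes in PICT minus OMCT; and osteoblast, cytokine, adipocyte and neutrophil genes in OMCT minus PCT. Then 3 did: complement genes in PICT minus PCT, and lipopolysaccharide and Schwann cell genes in OMCT minus PCT. With the level rule at the 75th percentile 6 moved inside, complement genes in PICT minus OMCT among them, and 2 outside. Of the 90 medians with a percentile under the settings first fixed, of which 58 stood apart, 50 did without a level rule, 54 with the level rule at the 75th percentile and 55 to 58 under the other settings run on lists. Signals below the pseudocount of 8.56 are near the negative controls, so differences of dim genes are the least certain.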

Other observations

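Genes of bone, TGF-beta response and immediate early response also differed between the tissues. Bglap (osteocalcin, made by osteoblasts) had an intensity of 266 in PICT, 434 in PCT and 10.1 in OMCT, while Spp1 had 3839.8, 58.5 and 1035. Dmp1 (a matrix protein of osteocytes and cementocytes) was at -2.10 in PICT minus PCT, and Omd (osteomodulin) at -2.89 and Alpl (alkaline phosphatase) at -2.40 in PICT minus OMCT. The osteoblast and cementoblast list thus split: in PICT minus PCT 1 of 14 genes was higher and 4 lower (median -0.50, percentile 1.16; as deposited 1 higher and 2 lower, median 0.10), and in PICT minus OMCT 3 were higher and 4 lower (median -1.02, percentile 0.02, which rests on leaving out dim members). In the TGF-beta list 6 of 17 genes were higher and 2 lower in PICT than in PCT (median 0.58, percentile 100). As deposited 9 were higher and 0 lower. Fn1 (fibronectin) was at 2.79, Inhba (the activin beta A subunit) at 2.65 and Tgfbr1 (a TGF-beta receptor) at 2.14. The 2 lower genes were Tgfb1, which encodes a TGF-beta ligand, at -1.40 and Ltbp1 at -1.27. The ligand genes Tgfb2 and Tgfb3 were at -0.49 and -0.84. These 4 genes were named after their values were seen. This list was also higher in OMCT than in PCT (6 higher and 0 lower, median 0.74, percentile 100). In PICT minus OMCT 1 gene was higher and 6 lower (median -0.12, percentile 25.3), so the rise over PCT was not particular to PICT. In the list of immediate early and heat shock genes, 6 of 26 were higher in PICT than in PCT (median 0.39, percentile 99.9). As deposited 14 were higher and 0 lower (median 0.99). Against OMCT 7 of 26 were higher (median 0.47, percentile 100), and 0 were lower in either comparison. Fos was at 1.77 and 1.96 and Egr2 at 1.80 and 1.66. The heat shock members Hspa1a, Hsph1, Dnaja1 and Dnajb1, named after their values were seen, were past 2-fold in neither. They were at -0.43, 0.38, 0.55 and 0.10 against PCT and at 0.61, 0.26, 0.54 and 0.98 against OMCT. Cell cycle genes had a median of -0.43 in PICT minus PCT (0.17 as deposited; percentile 0.08, which rests on leaving out dim members), with 2 of 27 lower and 0 higher (as deposited 3 higher and 0 lower).

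Antigen presentation and nerve genes also differed. Of 11 genes of MHC class II presentation 5 were higher and 0 lower in PICT than in PCT (median 0.62, percentile 99.9). Among them were RT1-DMb at 2.19 and Ciita (the class II transactivator) at 1.33, and 8 genes were higher as deposited. The class II list was also higher in OMCT than in PCT (4 higher and 0 lower, median 0.72, percentile 99.8). It did not stand apart in PICT minus OMCT (median -0.23, percentile 14.1). T and NK cell genes were mostly dim, with 5 of 22 higher and 0 lower in PICT than in PCT; Il7r (the interleukin 7 receptor) was at 3.37 and Cd8a at 3.04 with an intensity of 103 in PICT and 0.407 in PCT. Cd8a and Cd36 in PCT and Sox10 in PICT did not exceed the highest negative control of their array, so the sizes of their differences are not exact. Schwann cell and nerve genes were lower in PICT than in PCT for 7 of 15 and higher for 1 (median -0.81, percentile 0.40), and as deposited lower for 4 and higher for 2 (median -0.21), with Sox10 (a glial transcription factor) at -2.50, Gfra3 at -2.08 and Mbp (myelin basic protein) at -2.02. The median of -0.81 rests on 4 members above the median level. In PICT minus OMCT the nerve list did not stand apart (median -0.05, percentile 51.9), with 0 genes higher or lower by the 2-fold rule. In OMCT minus PCT its median was -0.50 (percentile 3.76), with 3 genes lower and 1 higher. The adipocyte list did not stand apart in PICT minus PCT (median -0.16 and 0.44 as deposited, percentile 28.0), with 3 of 15 genes higher and 0 lower. Among them were Fabp4 at 3.31 and Cd36 at 2.62, lipid carriers that macrophages and capillaries also make, while Adipoq, the fat cell hormone adiponectin, was dim everywhere (1.86 in PICT, 5.91 in PCT and 5.92 in OMCT) and was named after its values were seen. Complement and acute phase genes were lower in PICT than in OMCT for 4 of 19 and higher for 1 (median -0.50, percentile 1.53, which rests on leaving out dim members), and that 1 was A2m (alpha-2-macroglobulin) at 1.61.

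Among 30 skeletal muscle genes, Myh1 (a fast myosin heavy chain) had an intensity of 3339 in PICT, 2681 in PCT and 1620.4 in OMCT. The next brightest, Tnnt3, had 115, 46.1 and 80.7, and Acta1 had 5.28, 9.86 and 3.89; both were named after their values were seen. With other muscle genes this dim, whether the probe set measures Myh1 is in doubt and was not tested. Ribosomal protein genes had a median of -0.34 in PICT minus PCT (0.26 as deposited; percentile 1.21, which rests on leaving out dim members) with 0 of 32 past 2-fold (3 higher as deposited), and oxidative phosphorylation genes -0.16 (0.44 as deposited, percentile 11.4) with 0 of 47 (1 higher as deposited).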
